A study of Ovis aries with 54 samples.

How the data were processed

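Gene expression was measured by RNA sequencing in lung tissue of sheep (Ovis aries) from a series on a large-animal model of chronic obstructive pulmonary disease. Per the labels, total RNA was extracted with a column kit for small samples, the index was added at the poly-A priming step, pooled samples were amplified by template switching, and a sequencing adapter was added by transposase tagmentation and PCR. Each of 18 tissue pieces was sequenced as 3 libraries, giving 54 libraries. The treatment label put 7 pieces in the group exposed to porcine elastase and lipopolysaccharide (PE/LPS), 7 in the saline group and 4 in the control group. The sheep number and a letter code, LC or RA, were read from the sample titles. The meaning of the codes is not given in the sources used here, so they are used as written. In the 7 exposed sheep every PE/LPS piece was coded LC and every saline piece RA, so treatment and code are the same split there. Of the 4 control pieces, 2 were LC and 2 were RA, each from another sheep.

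The authors deposited 1 table of counts per gene, whole numbers that were not normalized, with a column for each library. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.10b, featureCounts, Subread 1.6.3 and edgeR 3.40.2, with no role or order. The genome build, the strand setting and the handling of molecular identifiers are not given in the sources used here. Reads of near-identical gene copies, of overlapping genes and of antisense partners may therefore be split or joined in ways that cannot be seen in the counts. Counts of 30184 genes were used, and 1 item is not reported here. Of the gene IDs, 25441 (84.3%) matched a symbol in a RefSeq gene table of the ARS-UI_Ramb_v3.0 assembly, which was used for names and no coordinates. No column was left without a sample.

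Library totals ran from 2777537 to 16215732 counts with a median of 9240328, except for library 1 of the PE/LPS piece of sheep 11 with 115109. The 3 libraries of a piece differed by more than counting noise: over genes with 50 or more counts in a pair of libraries, the index of dispersion was 7.26 to 18.5, where counting noise alone gives a value near 1. The library of 115109 counts was left out of this check. No library was therefore taken as a copy of another. In 16 of the 18 pieces each library correlated better with the others of its piece than with any library of another piece. The library of 115109 counts was left out here too, and its lowest correlation with a library of its own piece was 0.669. Because the 3 libraries come from 1 piece of 1 animal, their counts were summed and the piece was the unit of every test, with piece totals of 9653262 to 41946705. Floors cover counting error only, and the 95% intervals come from the fits over pieces.

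Whether the sheep numbers pair the pieces was checked before the fits were compared. The design text of the series describes saline and PE/LPS lobes of the same animals. The levels of 9 genes, chosen without the sheep numbers, split the 18 pieces into 2 sets each. At these the PE/LPS and saline pieces of the same number fell in the same set at all genes in 7 of 7 pairs, and the highest share for any other pair was 77.8%. Of the 5040 possible orders 1 gave a share as high (exact permutation p = 0.000198, the smallest the orders can give). Correlations of the deviations from group means, over genes above a minimum mean level, ran from -0.42 to 0.49 and were above 0.1 in 4 of 7 pairs. Their mean was 0.047, against -0.0043 for other pairs. Only 2 of 7 PE/LPS pieces correlated best with the saline piece of their number. The correlation within sheep fitted over the 18 pieces was -0.024. The sheep number was kept as a block.

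Differential expression was tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust fits, TMM scaling, filterByExpr with a minimum count of 10 and a total of 15) and Benjamini-Hochberg adjustment at 0.05. PE/LPS was compared with saline within sheep (sheep as a block), PE/LPS and saline each with control, and LC with RA among the control pieces. Whether the PE/LPS minus saline difference exceeded the LC minus RA difference in control sheep was tested with voom and a random block for the sheep in limma 3.58.1. DESeq2 1.42.0 and voom were run as alternatives, with other scalings and filters, single libraries, sheep left out in turn, fits with and without the sheep block, and code-matched controls. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Tested were 35 lists of marker and pathway genes (736 of 830 genes in the table), by camera with a preset correlation of 0.01 where 5 or more members were measured, and by camera with an estimated correlation, fry and exact tests of the list's mean over pieces. The comparisons, the lists, the tests and most alternatives were fixed before the data were examined, but the exact tests of list means were not. The named genes follow a rule fixed at the same time. Genes past the threshold come first, by size of change and from each list. Where fewer than 5 of a direction pass, the 5 with the smallest p are given for each comparison of the 3 groups, as not past the threshold, plus ELN, MMP12, SERPINA1, CXCL8, SCGB1A1 and SFTPC whatever their p. Members named within gene lists are among the 3 of that list with the smallest p in its direction and were chosen after their values were seen.

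The tests were tested on simulated data: 10 data sets per comparison were drawn for the real genes from the fitted means, library sizes and dispersions, with 200 genes changed by known folds. The fibrillar collagen list was also shifted lower. The changed genes were taken above a minimum mean level, and each gene was drawn independently. The shares below therefore do not cover genes of low level or correlation between genes. For PE/LPS against saline (16944 genes), 16.1% of genes changed 2-fold, 78.7% changed 4-fold and 92.4% changed 8-fold were recovered. For PE/LPS against control (18340 genes) the shares were 5.22%, 63.0% and 88.3%, for saline against control (18289 genes) 16.3%, 76.1% and 89.4%, for LC against RA (18063 genes) 1.79%, 27.8% and 70.2%, and for the exposure against the code difference (20719 genes) 0.149%, 8.21% and 36.2%. Unchanged genes made up 4.27%, 4.66% and 3.56% of the calls in the 3 group comparisons, against a nominal 5%. They made up 11.7% for LC against RA and 10.3% for the exposure against the code difference, so adjusted p-values of these 2 small designs are too small. The first data set drawn for LC against RA gave 15 unchanged genes among 87 calls (17.2%), above the limit set before it was run. The draws were then repeated for every comparison, and in 10 draws the share for LC against RA ran from 2.00% to 19.5%. The limit on the pooled share that replaced the first was set after these draws and covers the 3 group comparisons only. DESeq2 on the same simulated counts gave shares of 26.9% for PE/LPS against saline, 25.5% for PE/LPS against control, 21.6% for saline against control and 33.6% for LC against RA.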

Results

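The series compared lung tissue of sheep after exposure to porcine elastase, an enzyme that cuts elastin, and lipopolysaccharide (LPS), a bacterial cell wall component, with tissue exposed to saline in the same animals and with control sheep. The table held counts for 54 libraries, 3 from each of 18 tissue pieces: 7 PE/LPS pieces and 7 saline pieces from the same 7 sheep, and 4 control pieces from 4 other sheep. Piece totals were 9653262 to 37777824 counts in PE/LPS, 12760040 to 34762189 in saline and 23106036 to 41946705 in control tissue.

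The first comparison asked how PE/LPS tissue differed from saline tissue of the same sheep. HOXA7, a homeobox transcription factor, was measured at 13.2 ± 7.03 CPM (SD, n = 7) in PE/LPS and 0.947 ± 0.432 CPM in saline pieces, a log2 fold change of 3.69 (SE 0.56). It was higher in 7 of 7 sheep. EDNRB, an endothelin receptor of lung capillary endothelium, stood at 114 ± 74.6 against 55.9 ± 29.4 CPM (log2 fold change 0.99, SE 0.22), and HBB, the beta chain of haemoglobin, at 18.8 ± 18.5 against 5.27 ± 5.86 CPM (1.88, SE 0.41). The saline mean of HBB was 3.33 CPM without sheep 1. COL3A1, a fibrillar collagen, was measured at 175 ± 73.3 CPM in PE/LPS and 601 ± 539 CPM in saline (-1.51, SE 0.36), and was lower in 7 of 7 sheep. None of these passed the threshold: by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 16944 genes did, and the smallest adjusted p was 0.338, that of HOXA7. The fit without the sheep block did call HOXA7 (edgeR adjusted p = 0.00483), as did those without sheep 1 (edgeR adjusted p = 0.00614) and without a low-count filter (edgeR adjusted p = 0.0193).

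At an unadjusted p under 0.05 edgeR gave 976 genes (426 higher and 550 lower in PE/LPS) where 847.2 are expected by chance. DESeq2 called 47 genes (33 higher, 14 lower), among them HOXA7, COL3A1 and EDNRB (DESeq2 adjusted p = 4.10e-11, 0.00769 and 0.00787), and limma voom called 0. Besides HOXA7, EDNRB and HBB, the genes with the smallest p on the higher side were LOC114118586 (log2 fold change 2.41, SE 0.43) and LOC114115462 (4.15, SE 0.90), entries without a gene symbol. On the lower side they were ATP6V1C2, a proton pump subunit (-1.22, SE 0.24), HSD11B1L (-1.31, SE 0.30), COL3A1, TNFRSF6B, a decoy receptor for FAS ligand (-1.24, SE 0.30), and CCDC80 (-1.18, SE 0.29), each with an edgeR adjusted p of 0.771. HBB belongs to a family of near-identical globin genes, so its counts are uncertain. ELN, the gene of elastin, stood at 42.7 ± 27.4 CPM in PE/LPS and 95.2 ± 89.6 CPM in saline (-1.09, SE 0.37, lower in 6 of 7 sheep, edgeR adjusted p = 0.771), with a saline mean of 62.0 CPM without sheep 15. MMP12, macrophage elastase, had a log2 fold change of 0.94 (SE 0.50) and the neutrophil chemokine CXCL8 of 0.66 (SE 0.56). SERPINA1, which encodes the elastase inhibitor alpha-1 antitrypsin, had 0.25 (SE 0.74), the club cell gene SCGB1A1 -0.51 (SE 0.68) and the surfactant gene SFTPC -0.73 (SE 0.72), and none of these passed the edgeR threshold. With a sheep left out SFTPC ran from -1.11 (without sheep 1) to -0.23 (without sheep 8) and CXCL8 from 0.21 (without sheep 2) to 1.10 (without sheep 14). MMP12 was at 0.62 without sheep 14. By a normal quantile, somewhat too narrow for so few pieces, the median gene had a 95% interval of ± 0.65 on the log2 scale.

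**Figure D1:**
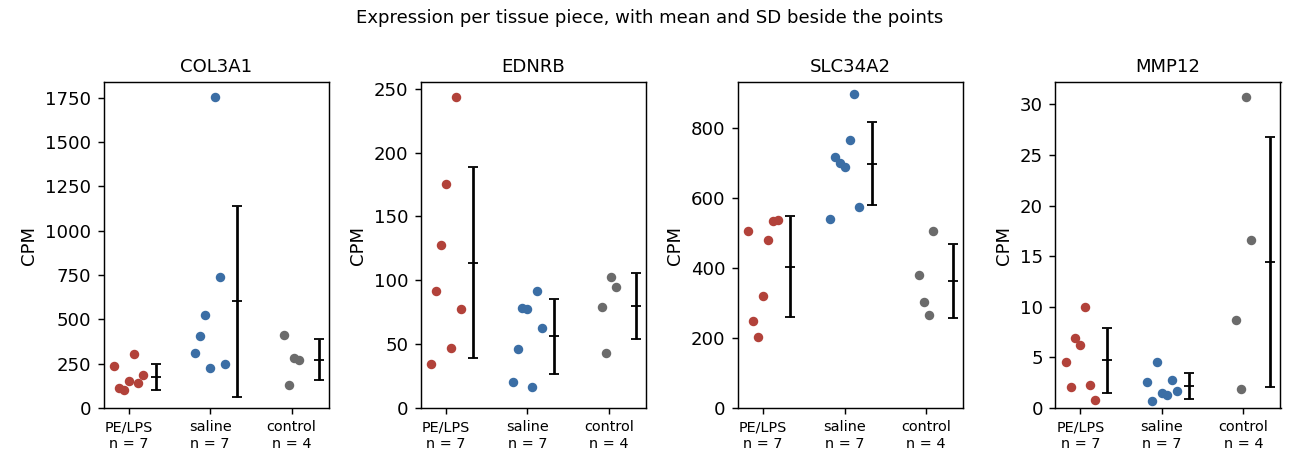
CPM (y axes, starting at 0) of COL3A1, EDNRB, SLC34A2 and MMP12 in each tissue piece (points) of the PE/LPS, saline and control groups, with the mean and SD beside the points. SLC34A2 averaged 403 CPM in PE/LPS, 697 in saline and 363 in control pieces, and MMP12 4.68, 2.15 and 14.4 CPM.

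Among 33 gene lists, camera with a preset correlation put 6 past an adjusted p of 0.05, 4 lower and 2 higher in PE/LPS. The ciliated cell list was lower (median log2 fold change -0.61 over 25 genes, 24 of them negative, camera adjusted p = 7.19e-08, and adjusted p = 0.475 with an estimated correlation). Its members include DNAI2, a dynein of the ciliary axoneme (6.16 ± 3.83 against 11.6 ± 3.33 CPM), and TEKT1 (18.0 ± 7.94 against 29.7 ± 7.96 CPM). The alveolar type 2 cell list, of the cells that make surfactant, was lower too (median -0.61 over 17 genes, 15 negative, camera adjusted p = 1.93e-06, and adjusted p = 0.475 with an estimated correlation). In it SLC34A2, a phosphate transporter, stood at 403 ± 144 against 697 ± 118 CPM and ABCA3, the lipid transporter of lamellar bodies, at 102 ± 40.3 against 158 ± 80.7 CPM. Between PE/LPS and control pieces this list did not pass (median 0.14, 11 of 17 positive, camera adjusted p = 0.819). The fibrillar collagen list was lower (median -0.55 over 21 genes, 17 negative, camera adjusted p = 5.21e-05, and adjusted p = 0.475 with an estimated correlation), with COL1A1 at 145 ± 42.7 against 544 ± 643 CPM (307 CPM without the saline piece of sheep 14). The secretory and mucous airway list was lower (median -0.68 over 20 genes, 15 negative, camera adjusted p = 0.00246, and adjusted p = 0.714 with an estimated correlation), with BPIFB1 at 90.1 ± 86.9 against 331 ± 375 CPM. Its means were 59.4 CPM without the PE/LPS piece of sheep 15 and 206 CPM without the saline piece of sheep 14, and control pieces averaged 87.8 CPM. The call of the secretory list within sheep ended without sheep 14 (median -0.082, camera adjusted p = 0.287) and without sheep 16 (-0.65, camera adjusted p = 0.163). Between PE/LPS and control pieces this list did not pass (median -0.30, 12 of 20 negative, camera adjusted p = 0.0805).

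The list of immediate early and heat shock genes was higher in PE/LPS (median 0.43 over 29 genes, 22 positive, camera adjusted p = 2.46e-05, and adjusted p = 0.475 with an estimated correlation). The chaperones HSPA6 and DNAJB1 stood at 50.3 ± 29.5 against 19.6 ± 23.7 CPM and at 104 ± 51.5 against 49.9 ± 10.9 CPM, and the saline mean of HSPA6 was 10.7 CPM without sheep 15. The interferon list was higher by a median of 0.16 over 25 genes, 18 positive (camera adjusted p = 0.0392, and adjusted p = 0.773 with an estimated correlation), with the chemokine CXCL9 at 275 ± 295 against 121 ± 66.3 CPM. The PE/LPS mean of CXCL9 was 165 CPM without sheep 2, whose piece stood at 939 CPM. The call of the interferon list ended without sheep 1, 14 or 15 (medians 0.13, 0.069 and 0.15, camera adjusted p = 0.0601, 0.287 and 0.160), and in the fit without the sheep block. Its median was 0.25 without sheep 8 and 0.080 without sheep 11, both past camera. Over all genes tested no member of a list passed the edgeR threshold. Adjusted over the list alone, 2 immediate early or heat shock genes and 1 fibrillar collagen gene did, and none of the other 4 lists past camera had such a member. In exact sign-flip tests of the list means over the 7 sheep, the ciliated, type 2 and heat shock lists each gave p = 0.0312 (adjusted p = 0.344, with 0.0156 the smallest p that 7 sheep allow). Exchanging treatment within pairs gave at least 6 lists past camera in 52 of 64 arrangements, the real one included, so chance could not be excluded for these calls. No list was tested between the letter codes in control sheep or against code-matched controls. Since PE/LPS pieces are LC and saline pieces RA, these list differences cannot be told apart from a difference between the codes.

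**Figure D2:**
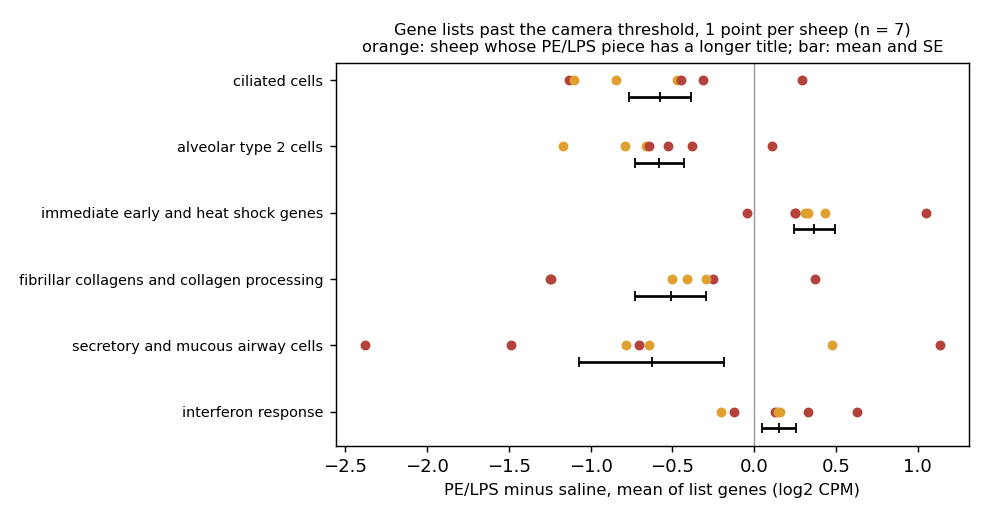
Difference between the PE/LPS and the saline piece of each sheep (points, n = 7) in the mean log2 CPM of the 6 gene lists past the camera threshold, with the mean and SE as a bar. Orange points are the 3 sheep whose PE/LPS piece has a longer title, and 6 of 7 sheep lie below 0 for the ciliated and alveolar type 2 lists.

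Lists of inflammatory cells did not pass. The neutrophil list had a median of -0.27 (camera adjusted p = 0.728), the macrophage list 0.24 (camera adjusted p = 0.728), where the mean was near 0, and the list of LPS and NF-kB response genes 0.10 (camera adjusted p = 0.397). The lists of elastic fibres (median -0.14, camera adjusted p = 0.0980), of matrix proteases (-0.01, camera adjusted p = 0.433) and of protease inhibitors (median 0.01 with a mean of -0.15, camera adjusted p = 0.456) did not pass either. Of the 7 PE/LPS pieces, 3 (sheep 2, 8 and 11) carry further characters after the letter code in their title, as does the control piece of sheep 9. These 4 pieces stood apart from the other 14 on the first principal component. In these 4 pieces the mean of the alveolar type 2 list was lower than in the other 14 by a difference of -0.70 (SE 0.12) and that of the ciliated list by -0.83 (SE 0.25, exact permutation test, adjusted p = 0.0167 for each). That test exchanges pieces over all groups, and 3 of the 4 are PE/LPS and none saline, so it does not separate title from treatment. Without sheep 2, 8 and 11, edgeR called 0 genes and 218 had an unadjusted p under 0.05, with no other tool run on those 4 sheep. The 6 lists stayed past camera, among 17 lists past it in that fit. The medians were -0.33 for the type 2 list, -0.39 for the ciliated list, -0.32 for fibrillar collagens and -1.10 for the secretory list (camera adjusted p = 0.00405, 6.34e-06, 6.34e-06 and 3.05e-06).

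**Figure D3:**
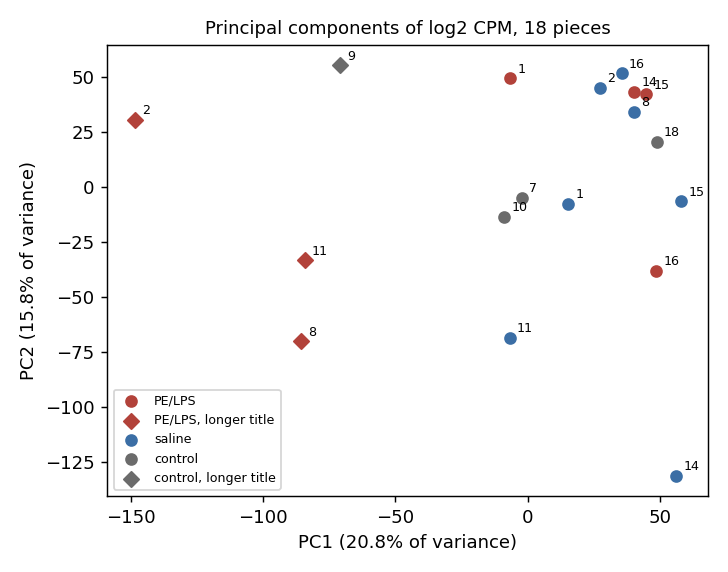
First and second principal components of log2 CPM (x axis 20.8% and y axis 15.8% of the variance) of the 18 tissue pieces, coloured by group and numbered by sheep, with diamonds for pieces with a longer title. The 4 diamonds lie between -148.5 and -70.8 on the first component and the other 14 pieces between -9.01 and 57.9.

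The second comparison set PE/LPS tissue against control sheep. The interferon list was higher in PE/LPS (median log2 fold change 0.30 over 25 genes, 23 positive, camera adjusted p = 4.53e-06, and adjusted p = 0.840 with an estimated correlation). In it IDO1, an enzyme of tryptophan breakdown, was measured at 8.68 ± 7.53 CPM (SD, n = 7) against 3.06 ± 0.242 CPM (n = 4), and CXCL9 at 275 ± 295 (165 without sheep 2) against 115 ± 36.1 CPM. The median of the list was 0.15, 0.18 and 0.46 without sheep 7, 10 and 18, past camera each time. The ciliated list was lower (median -0.34 over 25 genes, 22 negative, camera adjusted p = 0.000999, and adjusted p = 0.840 with an estimated correlation), with TEKT1 at 18.0 ± 7.94 against 28.1 ± 9.05 CPM. That call ended without the control piece of sheep 10 (median -0.062, camera adjusted p = 0.939). The median was -0.21 without sheep 2 and -0.58 without sheep 9, both past camera. The oxidative phosphorylation list (median -0.22 over 30 genes, 25 negative, camera adjusted p = 0.00701) and the fibrillar collagen list (median -0.14 over 21 genes, 14 negative, camera adjusted p = 0.0484) were lower, each with an adjusted p = 0.840 with an estimated correlation. The call of fibrillar collagens ended without sheep 1, 7, 8, 10, 15 or 18 (camera adjusted p = 0.0590 to 0.521). Their median ran from -0.043 without sheep 18 to -0.51 without sheep 9, with -0.057 without sheep 7. It was -0.15 to -0.18 without sheep 1, 8, 10 or 11 and -0.21 to -0.26 without sheep 2, 14, 15 or 16. The call of the oxidative phosphorylation list ended without sheep 8, 9 or 16 (medians -0.15, -0.049 and -0.11, camera adjusted p = 0.130, 0.830 and 0.440), and its median was -0.34 without sheep 18. It also ended without the 4 pieces with a longer title (median -0.0081, camera adjusted p = 0.839, with a camera direction of higher). The medians without them were 0.49 for the interferon list and -0.34 for fibrillar collagens, both past camera. Of 100 splits of these pieces, 74 gave at least 4 lists, so chance could not be excluded.

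No single gene passed. The quasi-likelihood test of edgeR called 0 of 18340 genes, 234 had an unadjusted p under 0.05 where 917 are expected by chance, and DESeq2 and voom called 0. Other splits of these pieces gave a median of 497 genes at an unadjusted p under 0.05. The genes with the smallest p on the higher side were LOC101104893 (log2 fold change 4.13, SE 1.09), LOC105610456 (3.94, SE 1.14), LOC121818148, LOC114115479 and GCG, the glucagon precursor. The last 3 had 0 counts in all control pieces. Against a floor of 3 counts over the control group they were at least 21.7-fold, 30.99-fold and 23.1-fold higher in PE/LPS, at 0.530, 0.756 and 0.563 CPM over the pooled group, and 31.2% to 42.3% of those counts came from 1 piece. On the lower side stood LOC114110673 (-3.93, SE 0.95), LOC101113032 (-1.20, SE 0.32), LOC114118278 (-4.26, SE 1.20), KEF53_t22 (-1.83, SE 0.58) and EPS8L3 (-2.03, SE 0.64). Single control pieces weigh on some of these. LOC105610456 had counts in the control piece of sheep 18 alone of the 4, so its fold cannot be measured without that piece. The control mean of LOC101104893 was 0.060 CPM, so its fold rests on few counts. KEF53_t22 was at -0.77 without sheep 9 and EPS8L3 at -0.95 without sheep 10. The control mean of LOC114118278 was 3.56 CPM, and 1.15 CPM without sheep 7, with the lowest control piece at 0.032 CPM. That of LOC114110673 was 29.2 CPM, and 15.4 CPM without sheep 9, with the lowest control piece at 1.68 CPM. All PE/LPS pieces are LC. Against the LC control pieces alone KEF53_t22 was at -0.43 (SE 0.62) and EPS8L3 at -2.71 (SE 0.68). MMP12 was measured at 4.68 ± 3.23 CPM in PE/LPS and 14.4 ± 12.4 CPM in control (-1.60, SE 0.64), and SERPINA1 at 1.27 ± 0.674 and 2.77 ± 1.41 CPM (-1.10, SE 0.54). MMP12 was at -0.92 without sheep 10 (control mean 9.01 CPM) and SERPINA1 at -0.73 without sheep 18. Against the LC control pieces alone MMP12 was at -2.33 (SE 0.63) and SERPINA1 at -1.45 (SE 0.68). ELN (-0.14, SE 0.52), CXCL8 (0.08, SE 0.65), SCGB1A1 (0.17, SE 0.75) and SFTPC (-0.04, SE 0.72) differed by less than their error. The smallest edgeR adjusted p in this comparison was 0.99994.

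The third comparison set saline tissue of the exposed sheep against control sheep. The alveolar type 2 list was higher in saline tissue (median log2 fold change 0.54 over 17 genes, 16 positive, camera adjusted p = 2.26e-08, and adjusted p = 0.113 with an estimated correlation). SLC34A2 stood at 697 ± 118 CPM (SD, n = 7) against 363 ± 106 CPM (n = 4), SFTPB, a surfactant protein, at 3029 ± 980 against 1474 ± 660 CPM and LAMP3 at 479 ± 72.7 against 301 ± 75.9 CPM. An exact permutation test of the mean of this list over pieces gave p = 0.00303, the smallest possible with 7 and 4 pieces, and an adjusted p of 0.103 over 34 lists. The list of B and plasma cells was higher (median 0.60 over 20 genes, 15 positive, camera adjusted p = 0.00471, and adjusted p = 0.771 with an estimated correlation), with CD22 at 10.4 ± 5.12 against 5.31 ± 2.10 CPM. The list of cholesterol and lipid synthesis was higher (median 0.30 over 24 genes, 18 positive, camera adjusted p = 0.00897, and adjusted p = 0.771 with an estimated correlation), with SQLE, a sterol synthesis enzyme, at 42.3 ± 9.20 against 28.4 ± 2.87 CPM. The oxidative phosphorylation list was lower (median -0.35 over 30 genes, 28 negative, camera adjusted p = 1.18e-06, and adjusted p = 0.953 with an estimated correlation), with NDUFB3 at 95.9 ± 33.5 against 172 ± 77.5 CPM. Without the control piece of sheep 9 the medians were 0.36 for B and plasma cells and 0.18 for cholesterol and lipid synthesis, both past camera. The median for B and plasma cells was 0.40, 0.23, 0.38 and 0.30 without sheep 8, 10, 11 and 16, past camera each time. The cholesterol call ended without sheep 8 or 18 (medians 0.20 and 0.26, camera adjusted p = 0.0677 and 0.0526). The oxidative phosphorylation median was -0.53, -0.57 and -0.57 without sheep 7, 16 and 18, past camera each time. Of 100 splits of these pieces, 92 gave at least 4 lists, so chance could not be excluded.

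edgeR's quasi-likelihood test called 0 of 18289 genes, 898 had an unadjusted p under 0.05 where 914 are expected by chance, DESeq2 called 6 (2 higher, 4 lower) and voom 0. Other splits of these pieces gave a median of 616 genes at an unadjusted p under 0.05. MMP12 had the smallest p, at 2.15 ± 1.28 CPM in saline and 14.4 ± 12.4 CPM in control (log2 fold change -2.75, SE 0.56, edgeR adjusted p = 0.939, DESeq2 adjusted p = 0.0109). In control sheep MMP12 stood at 30.7 and 16.6 CPM in the LC pieces and at 8.65 and 1.81 CPM in the RA pieces (log2 difference 2.17, SE 0.71, edgeR adjusted p = 0.987). All saline pieces are RA, and against the 2 RA control pieces the log2 fold change of MMP12 was -1.29 (SE 0.66, edgeR adjusted p = 0.581). MCP-3, a monocyte chemokine, stood at 0.564 ± 0.483 against 7.67 ± 10.5 CPM (-3.76, SE 0.89), and at -2.11 without sheep 9 (control mean 2.48 CPM). LOC114110673 (-4.41, SE 0.89), LOC114109014 (-1.65, SE 0.38) and LOC101113032 (-1.49, SE 0.35) were the others on the lower side. The control mean of LOC114110673 was 29.2 CPM, and 15.4 CPM without sheep 9. On the higher side were KCNJ5, a potassium channel (4.72, SE 1.15), TMEM178A (2.64, SE 0.67), FCGR2B, an inhibitory receptor for immunoglobulin G (0.99, SE 0.26, at 59.9 ± 19.7 against 29.8 ± 4.22 CPM), TMEM158 (1.39, SE 0.36) and PLCXD1 (1.11, SE 0.29). The control means of KCNJ5 and TMEM178A were 0.060 and 0.285 CPM, so their folds rest on low counts. ELN stood at 0.99 (SE 0.56), SERPINA1 at -1.04 (SE 0.72), CXCL8 at -0.51 (SE 0.69), SCGB1A1 at 0.10 (SE 0.41) and SFTPC at 0.38 (SE 0.48). ELN was at 0.40 without sheep 15 and 1.66 without sheep 18, and SERPINA1 at -0.68 without sheep 18. SFTPC ran from 0.19 (without sheep 10) to 0.54 (without sheep 9).

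Since PE/LPS and the code LC coincide in the exposed sheep, the codes were compared in control sheep, which had no exposure. HOXA7 stood at 8.39 and 11.0 CPM in the 2 LC pieces and at 0.528 and 1.70 CPM in the 2 RA pieces, a log2 difference of 3.13 (SE 0.73, edgeR adjusted p = 0.987, DESeq2 adjusted p = 0.0268). Of the exposed sheep, sheep 1 was the exception, with 1.495 CPM in its PE/LPS piece and 1.27 CPM in its saline piece. edgeR called 0 of 18063 genes between the codes, 670 had an unadjusted p under 0.05 where 903 are expected by chance, DESeq2 called 55 and voom 1. Without sheep 7, 2627 genes had an unadjusted p under 0.05 and edgeR called 5, and without sheep 9, 10 or 18 they were 539, 752 and 518, with 2, 12 and 33 called. The difference between PE/LPS and saline tissue exceeded the code difference past the threshold at 0 of 20719 genes by limma voom (1264 at an unadjusted p under 0.05, with 1036 expected by chance), and at 0 by edgeR without the random block. For HOXA7 that excess was 0.074 (SE 1.45), and for COL3A1 it was -1.86 (SE 0.84, limma adjusted p = 0.729). By a normal quantile, somewhat too narrow here too, the median gene had a 95% interval of ± 1.51 on the log2 scale in this test.

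**Figure D4:**
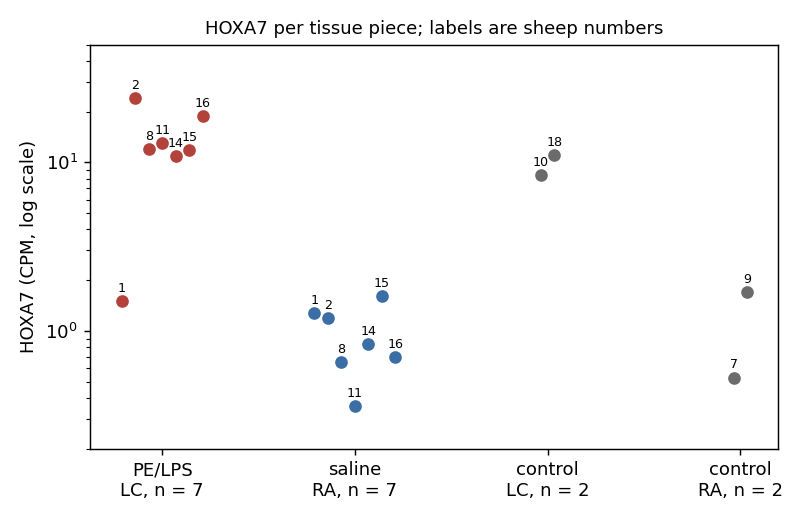
HOXA7 in CPM (y axis, log scale) in each tissue piece (points, numbered by sheep), by group and letter code. In control sheep the LC pieces stand at 8.39 and 11.0 CPM and the RA pieces at 0.528 and 1.70 CPM, and the PE/LPS piece of sheep 1 at 1.495 CPM.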

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

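Of the tests in this part, those on HOXA7, on library totals and on sheet numbers were chosen after the results were seen, and the fits that count each library as a replicate were added after the data were examined; the test on the cartilage, mesothelium and skeletal muscle list and the splits of those fits were set down before their results.

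A piece far from the rest of its group was found in 5 of 107 groups examined, where chance gives about 5.35. LOC105610456 stood at -1.10 log2 CPM in the control piece of sheep 18, with the other 3 control pieces at -3.77, the value of 0 counts. LOC101113032 stood at 4.60 log2 CPM in the control piece of sheep 9, with the others between 3.84 and 3.90. KCNJ5 stood at -2.11 log2 CPM in the saline piece of sheep 11, with the other 6 between 0.07 and 1.70. PLCXD1 stood at 3.25 log2 CPM in the control piece of sheep 10, with the others between 4.03 and 4.06. The mean of the fibrillar collagen list stood at -0.65 log2 units in the control piece of sheep 9, with the others between 0.11 and 0.25.

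HOXA7 was higher in the PE/LPS than in the saline piece of every exposed sheep, at a log2 fold change of 3.69. An exchange of the pieces of sheep 1, whose PE/LPS piece was low at 1.495 CPM, is argued against by its saline piece, which was also low at 1.27 CPM where the other 6 LC pieces began at 10.8 CPM. A candidate explanation is a difference between the letter codes that needs no exposure, since LC exceeded RA by 3.13 (SE 0.73) in control sheep. Whether exposure adds to it stays open: the excess over the code difference was 0.074 (SE 1.45), and 2 control pieces per code leave that interval wide.

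The 4 pieces with a longer title stood apart on the first principal component. Lower totals are argued against: 0 of the 4 had totals above the median of the other 14, but after every piece was thinned to 9653262 counts, 4 of the 4 still lay beyond the others, at -61.8 or lower against -14.4 or higher. The later sheet numbers are argued against as well, because the saline piece of sheep 1, which shares them, lay at 15.2 inside the range of the rest, and 2 of the 4 have earlier numbers. A rise of the cartilage, mesothelium and skeletal muscle list as a whole is argued against by a list mean that differed by -0.23 (SE 0.40). The list pools markers of these tissues, so RNA from only 1 of them stays open. What the further characters stand for, such as another site or handling of the tissue, was not tested.

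Counting each library as a replicate gave 2345 genes between PE/LPS and saline tissue where the test on pieces gave 0. Of the 64 exchanges of treatment within pairs, 20 gave as many under that count, the real one included, and the highest other gave 6165, so chance could not be excluded. A candidate explanation is that the libraries of 1 piece share the level of that piece, since the median of the other exchanges was 951 genes. Whether exposure adds to it stays open: 30 of the other exchanges gave at least 50% as many calls as the real one.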

How the results depend on the processing

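Fits without sheep 2, 8 and 11, without pieces with a longer title, with each library counted as a replicate, and exact tests of list means were chosen after seeing the data. For PE/LPS against saline, edgeR called 0 genes in the main test, and 17 of 23 alternatives, voom among them, gave 0. edgeR called 1 without a low-count filter, 1 with no replicate block and 0 to 1 with a sheep left out (1 without sheep 1), in each case HOXA7 (adjusted p = 0.0193, 0.00483 and 0.00614, and from 4.10e-11 to 0.99996 over all alternatives). DESeq2 called 47, libraries as units with the piece as a random block 460, and each library counted as a replicate 2345. The block changed no other call of a gene. Against control, PE/LPS tissue had 0 calls, but 1 with libraries as units (KEF53_p11, chosen like the next genes after values were seen) and 7 with each library counted as a replicate. Saline tissue against control had 0, but 6 by DESeq2, 20 with libraries as units and 754 with each library counted as a replicate. LC against RA had 0, but 55 by DESeq2, 1 by voom (TPT1), 94 without a filter, and 2 to 33 with a sheep left out (5 without sheep 7: LOC114114247, LOC114114873, LOC114115623, LOC101119545 and TRNAR-UCG_7, 2 without sheep 9: LOC114111412 and LOC101103658, 12 without sheep 10 and 33 without sheep 18), which leaves 1 piece of a code that is assumed to vary like the rest. For the exposure against the code difference, 1 gene (TRNAG-GCC_44) passed without a filter and 0 in the other 6 alternatives. DESeq2 and these 2 small designs exceeded the nominal share of false calls on simulated data. The fits with libraries as units use 1 correlation for all genes. No simulation or split was run for them, so their share of false calls is unknown.

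Gene lists past the threshold went from 6, 4 and 4 in the 3 comparisons to 0, 0 and 0 with camera's estimated correlation, to 0, 0 and 0 with fry and to 0, 0 and 0 by exact tests, whose smallest possible p (0.0156 within sheep, 0.00303 against control) passes only if several lists share it. With a sheep left out they ran from 6 to 11 for PE/LPS against saline (10 without sheep 2, 11 without sheep 8), 3 to 9 for PE/LPS against control (8 without sheep 9, 9 without sheep 18) and 4 to 9 for saline against control (7 without sheep 2, 9 or 11, 8 without sheep 10 or 15, 9 without sheep 16). Without sheep 2, 8 and 11 there were 17, without the 4 pieces with a longer title 10, and without the control piece of sheep 9, 7. With no replicate block there were 5. The oxidative phosphorylation list in PE/LPS against control turned to higher by camera without the 4 pieces with a longer title, at a median of -0.0081. Of 1055 values of named genes, 965 kept direction and side of the threshold, 51 passed it and 39 changed sign.

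None that changed sign was past the threshold on either side. Between PE/LPS and saline tissue they were MMP12 with only library 1 (-0.10), SERPINA1 with a sheep left out (-0.23 to 0.62) and with no replicate block (-0.076), CXCL8 without sheep 1, 2 and 8 (-0.18) and without sheep 2, 8 and 11 (-0.20). Likewise SCGB1A1 changed sign with a sheep left out (-1.01 to 0.0079), with no replicate block (0.057), without sheep 1, 2 and 8 (0.65) and without sheep 2, 8 and 11 (0.56), and SFTPC without sheep 2, 8 and 11 (0.0098). Between PE/LPS and control tissue they were ELN with a sheep left out (-0.41 to 0.54) and without pieces with a longer title (0.14), CXCL8 with only library 1 (-0.44) and with a sheep left out (-0.42 to 1.03). So did SCGB1A1 by voom (-0.50), with libraries as units (-0.22), with a sheep left out (-0.38 to 0.55), with code-matched controls (-0.14) and with the code as a covariate (-0.13), and SFTPC with only library 1 (0.073), with a sheep left out (-0.67 to 0.17), with code-matched controls (0.42), with the code as a covariate (0.43) and without pieces with a longer title (0.67). Between saline and control tissue they were CXCL8 with a sheep left out (-1.24 to 0.45) and SCGB1A1 with only library 2 (-0.0033) and with a sheep left out (-0.18 to 0.47). The cause was not tested for any of these changes, except that leaving out pieces leaves fewer of them.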

Other observations

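The split tests on the 3 counts of genes past the threshold by edgeR, and on the DESeq2 count for PE/LPS against control, were chosen after those counts of 0 were known. The other split tests were set down before. The comparison of lists between pieces with and without a longer title was chosen after the data were seen.

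Some genes called between PE/LPS and saline tissue by DESeq2 and not by edgeR are named here, chosen after their values were seen. On the lower side were MSLN, a marker of mesothelium (log2 fold change -1.96, adjusted p = 0.0141), BPIFB2 (-2.79, adjusted p = 0.0102) and ANKRD1 (-1.92, adjusted p = 0.0108). On the higher side were the neutrophil chemokine receptor CXCR2 (1.38, adjusted p = 0.0289) and EDN3, a ligand of endothelin receptors (1.45, adjusted p = 0.0390). On simulated counts of this comparison 26.9% of DESeq2 calls were unchanged genes. Of 12 other HOX genes, chosen likewise, 7 were on the higher and 5 on the lower side between PE/LPS and saline tissue (log2 fold changes -0.50 to 1.07), each with an edgeR adjusted p of 0.775 or more. TPT1 was the 1 gene that voom called between the codes in control sheep (log2 difference 6.39, SE 0.60, voom adjusted p = 0.0364), and it is also among the 9 genes whose level split the pieces into 2 sets that followed the sheep.

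Beyond the ciliated and type 2 lists, no list differed past the threshold of 0.05 between the 4 pieces with a longer title and the other 14. Next in p were the complement list (-0.54, SE 0.17, adjusted p = 0.0639 by an exact permutation test) and the list of antioxidant enzymes (-0.52, SE 0.16, adjusted p = 0.0639 by the same exact test, which leaves the groups aside). Of the counts of the 4 pieces 14.3% to 16.4% fell on entries without a symbol, against 11.1% to 14.2% in the other 14.

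Other splits of the same pieces were used to ask whether chance can be excluded. Every split reaches a count of 0, so for the real counts of 0 they say nothing. For the counts above 0 chance could not be excluded. Within the 7 sheep, 64 exchanges within pairs were run. The real 0 genes were reached in 64 of them (highest other 141), the 976 genes at an unadjusted p under 0.05 in 17 (highest other 3705), the 6 lists in 52 (highest other 16) and the 47 DESeq2 calls in 14 (highest other 2031). The exchange with 3705 genes swapped treatment in sheep 2, 8 and 16 and kept it in the other sheep. That count is several times the real one, which points to a structure of the samples. On the second principal component the PE/LPS piece lay below the saline piece in sheep 2, 8 and 16 and above it in the others. Between PE/LPS and control pieces, 100 splits were drawn. The real 0 genes were reached in 100 (highest other 1430), 234 genes at an unadjusted p under 0.05 in 93 (highest other 4928), 4 lists in 74 (highest other 17) and 0 DESeq2 calls in 100 (highest other 2926). The split with 1430 genes set the PE/LPS pieces of sheep 14, 15 and 16 and the control piece of sheep 18 apart, which also points to a structure of the samples. On the first principal component these were the highest of the PE/LPS and control pieces, at 40.2 to 48.6. Between saline and control pieces, 100 splits were drawn. The real 0 genes were reached in 100 (highest other 2), 898 genes in 33 (highest other 3060), 4 lists in 92 (highest other 20) and 6 DESeq2 calls in 43 (highest other 612).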
